A study of Mus musculus and Saccharomyces cerevisiae with 99 samples.

How the data were processed

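Mouse E14 embryonic stem cells were either wild type (WT) or carried histone-binding mutations in a replication protein, MCM2 (labelled MCM2_2A in the RNA libraries and MCM22A in the H3K9me3 library, read here as 1 genotype) or POLA1 (labelled POLA1_hbm). MCM2 is a subunit of the replicative helicase and POLA1 the catalytic subunit of DNA polymerase alpha. The series lists 99 samples, and 11 with count files were used: 6 total RNA-seq libraries (2 WT, 2 MCM2_2A, 2 POLA1_hbm) and 5 H3K9me3 CUT&TAG libraries (2 WT, 2 POLA1_hbm, 1 MCM22A). The other samples, which include other histone marks and yeast, were not analysed here. The labels do not say that replicates are separate cultures or clones, so each p-value refers to these samples alone.

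The authors deposited raw counts per gene and per repeat subfamily. Their notes name mm10, STAR, Bowtie2, featureCounts and DESeq2 for the whole series without a version or a role for each assay. The strand setting, the treatment of reads that map to several places, the annotation release, the removal of duplicates and the part of a gene counted in the H3K9me3 libraries are not stated. Each file held 53715 genes and 1153 repeat subfamilies of 14 classes, and all values were whole numbers. Symbols came from the H3K9me3 files. Positions and biotypes came from GENCODE vM21 on GRCm38 (mm10), matched by gene ID without its version, which placed 53620 genes. No spike-in is named and no input library was used, so every value is relative to the library total.

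RNA totals were 32900024 and 41966019 counts (WT), 33629867 and 35517986 (MCM2_2A), and 42871796 and 43375749 (POLA1_hbm). H3K9me3 totals were 3821148 and 3264037 (WT), 4634929 and 2632453 (POLA1_hbm) and 6360125 (MCM22A). A floor of 3 counts per library was 0.0696 to 0.0901 counts per 1e+06 counts of the library (CPM) in the RNA libraries. Floors and 95% intervals cover counting error only.

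Differential tests used edgeR 4.0.16 in R 4.3.3, with filterByExpr defaults, TMM scaling, glmQLFit with 1 fit over all libraries of an assay, and 2-sided glmQLFTest, with Benjamini-Hochberg adjustment over genes and repeats together and a threshold of 0.05. The RNA fit tested 19610 features (18756 genes and 854 repeats) with 3 residual degrees of freedom and a common biological coefficient of variation of 0.104. The H3K9me3 fit tested 7106 features (6035 genes and 1071 repeats) with 2 residual degrees of freedom and a coefficient of 0.143. The single MCM22A library was assumed to vary like the other groups. The fit shares its estimate of spread across features, so a feature's error and p-value can be smaller than its own replicates would give. In H3K9me3, IAPEz-int was called with 88680 and 67100 CPM in WT against 69400 and 52490 in POLA1_hbm. With 2 residual degrees of freedom, the smallest H3K9me3 p-values rest on that shared estimate. CPM in the text use TMM-scaled library sizes, errors of log2 fold changes are standard errors (SE), and counts of calls are at the adjusted threshold.

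On simulated counts with 100 features changed 2-fold, the test recovered 51 (MCM2_2A against WT), 66 (POLA1_hbm against WT) and 65 (POLA1_hbm against MCM2_2A) in RNA, and 16, 20 and 16 for POLA1_hbm against WT, MCM22A against WT and POLA1_hbm against MCM22A in H3K9me3. At 4-fold it recovered 90, 89, 92, 65, 56 and 62. Wrong calls made up 7.84, 7.74, 8.19, 8.99, 9.52 and 0% of all calls.

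Lists of genes were written before the data were examined: naive pluripotency, formative and primed pluripotency, 2-cell-like, germline, endoderm, mesoderm, neuroectoderm, trophectoderm, fibroblast, replisome and nucleosome assembly, H3K9 methylation and retroviral silencing, replication-dependent histones, p53 targets, interferon response, imprinted, Y-linked, glycolysis, cholesterol synthesis and ribosomal protein genes. The repeat groups, written at the same time, were IAP, ETn/MusD, MERVL, MMERVK10C, MuLV-like, VL30, GLN, L1Md and satellite subfamilies, the ERVK, ERV1, ERVL, ERVL-MaLR, L1, L2, Alu/B1, B2, B4 and MIR families, and DNA transposons. Groups built on name prefixes hold more than their namesakes: the GLN prefix also takes in RLTR10 to RLTR19, which overlaps the MMERVK10C group, and the MuLV-like prefix takes in RLTR40 to RLTR49. The histone list holds the pseudogene Hist3h2bb-ps, and the ribosomal list holds the related Rps12l1 and Rpl22l1. Lists and repeat groups were tested with limma 3.58.1 camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Camera sets a group against all other tested features, so a difference between repeats and genes as a whole enters each repeat group.

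The genes named were chosen by a rule written before the data were examined. It takes up to 8 RNA genes per direction in each mutant against WT (5 between the mutants) with the largest change among those called. These needed an absolute log2 fold change of at least 1, a mean log2 CPM of at least 1 and no overlap between groups. H3K9me3 genes (5 per direction) and repeats (5 per direction, 3 between the mutants in RNA) needed only a call and that mean. Small changes and overlapping groups are therefore named among them. Up to 4 called members of lowest p in each list were added, and Pola1 and Mcm2 were always included. Predicted genes and pseudogenes were skipped for RNA by their symbols. Clone-based names and pseudogenes known only by biotype were skipped in the same way, which the written rule did not state.

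Effects of the mutants were compared as Pearson correlations of log2 fold changes, against 100 simulated data sets in which the mutants shared the WT libraries and had no effects. RNA and H3K9me3 fold changes of repeats were compared with 100000 permutations. DESeq2 1.42.0, RLE scaling, scaling by total counts, no filter, a stricter filter (1 CPM in 2 libraries), a fit to the compared libraries alone, a minimum log2 fold change of 1 and leaving out each library were the alternatives. A term for a tag in the H3K9me3 file names, scaling on genes alone and adjustment over repeats alone were tried where they applied. Fits without processed pseudogenes, fits to protein-coding genes and repeats, the H3K9me3 fits to the compared libraries alone and total-count scaling of the named H3K9me3 features were chosen after seeing the data. So was setting each mutant against a different WT library for the shared effects. Named features were refitted with DESeq2, RLE scaling, no filter, the compared libraries alone, each library left out and, for H3K9me3, total counts. The stricter filter and the minimum fold change were applied to counts of calls alone. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 served for the sequence comparison and the plots.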

Results

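RNA abundance and H3K9me3 signal were compared between WT embryonic stem cells and cells with histone-binding mutations in MCM2 or POLA1, to ask how the mutants differ from WT in gene expression and in this silencing mark. Repeats took 3.95 to 5.21% of the counts in the 6 RNA libraries and 92.6 to 93.6% in the 5 H3K9me3 libraries.

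MCM2_2A against WT RNA asks which genes change when MCM2 carries its histone-binding mutation. Serpina3m (ENSMUSG00000079012, chromosome 12: 104338486 to 104394257), one of a cluster of similar protease inhibitor genes, rose by a log2 fold change of 6.20 ± 0.41 (SE, n = 2 libraries per genotype). This gene stood at 0.180 and 0.0716 CPM in the WT libraries and at 7.30 and 10.9 CPM in the MCM2_2A libraries (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.000437). Tbx3 (ENSMUSG00000018604, chromosome 5: 119670669 to 119684724), a transcription factor of naive pluripotency, rose by 1.67 ± 0.12, from 11.3 and 11.7 to 32.9 and 40.1 CPM (adjusted p = 0.000666). Mcm2 RNA itself (ENSMUSG00000002870, chromosome 6: 88883474 to 88898780) changed by -0.74 ± 0.09, from 462 and 517 to 273 and 312 CPM (adjusted p = 0.00415). Pola1 RNA (ENSMUSG00000006678, chromosome X: 93304767 to 93632155) showed no call at 0.13 ± 0.08 (adjusted p = 0.399). Without MCM2_2A replicate 1 the Mcm2 change was -0.65 with an adjusted p of 0.0704.

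The cytochrome gene Cyp2b23 rose by 1.95 ± 0.21, the ankyrin-repeat gene Ankrd33b by 1.85 ± 0.16, and the glutathione peroxidase gene Gpx2 by 1.83 ± 0.18 on the log2 scale. Each was higher in both MCM2_2A libraries than in both WT libraries, as the rule for naming these genes required. The mucin gene Muc3 (2.99 ± 0.36) and the gluconeogenic Fbp2 (2.30 ± 0.28) were called higher too, but not without MCM2_2A replicate 2 (adjusted p = 0.0561 and 0.0645). The collagen receptor Ddr2 (2.38) lost its call without MCM2_2A replicate 2 or either POLA1_hbm replicate (adjusted p 0.0641 to 0.142). The meiotic cochaperone Fkbp6 (2.13) lost it without any one of the MCM2_2A or POLA1_hbm libraries (0.0784 to 0.148). Among genes called lower, the smooth-muscle genes Acta2 (-3.58 ± 0.60) and Tagln (-2.90 ± 0.43), Csf1 (-2.73), Acta1 (-2.69), the keratin Krt8 (-2.18 ± 0.35), Anxa3 (-2.26) and Thbs1 (-2.19) lost their calls without MCM2_2A replicate 1, MCM2_2A replicate 2, POLA1_hbm replicate 1 or POLA1_hbm replicate 2 (adjusted p 0.053 to 0.261). WT varied in these genes: Tagln had 135 and 41.6 CPM and Acta2 34.8 and 7.59 CPM in the WT libraries. Prss23 (-2.63) lost its call without MCM2_2A replicate 1 (0.0715) or replicate 2 (0.0645).

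In MCM2_2A, 2 of 22 tested naive pluripotency genes rose and 0 fell (3 and 0 adjusted over the list alone), Tbx3 and Prdm14 (0.62 ± 0.12). For the list, camera gave adjusted p = 0.00142 upward, and adjusted p = 0.713 with an estimated correlation. Of 19 formative and primed genes, 2 rose (Nodal 0.57, Etv4 0.62) and 2 fell (Fgf8 -1.79, Zic2 -0.61), or 5 and 5 adjusted over the list alone (camera adjusted p = 0.803, upward although the median was -0.058 and the mean -0.038). Of 13 genes of the 2-cell-like state, 1 rose, the multi-copy Usp17lb (2.06 ± 0.36), or 10 adjusted over the list alone (camera adjusted p = 2.1e-06, and adjusted p = 0.469 with an estimated correlation). Of 24 germline genes, 5 rose, among them the ribosomal retrogene Rpl10l (1.31 ± 0.13), the RNA-binding Dazl (1.16 ± 0.17), Tex19.1 (0.83) and Stk31 (1.04), or 7 up and 2 down adjusted over the list alone (camera adjusted p = 0.000145, and adjusted p = 0.469 with an estimated correlation). Tbx3 and Rpl10l kept their calls in every refit run for named genes (DESeq2, RLE scaling, no filter, the compared libraries alone and each library left out). Prdm14, Zic2, Fgf8, Usp17lb, Tex19.1 and Stk31 were not called without any one of the MCM2_2A or POLA1_hbm replicates (adjusted p 0.0567 to 0.248). Nodal and Etv4 were not called without either MCM2_2A replicate (0.0645 to 0.0957), nor Dazl without MCM2_2A replicate 2 (0.105) or POLA1_hbm replicate 1 (0.052). Without any one of those 4 libraries the 4 lists held 0 to 2 calls each, and without WT replicate 2 they held 11, 13, 6 and 13.

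Among lineage lists in MCM2_2A, 2 of 21 endoderm genes rose and 3 fell (3 and 3 adjusted over the list alone), with Krt8, Krt19 (-0.93) and Krt18 (-2.01) down and Pdgfra (1.46) up. Of 17 mesoderm genes 2 rose (Bmp4 0.51, Kdr 1.10) and 1 fell (T -1.81), or 5 and 3 adjusted over the list alone. Of 13 neuroectoderm genes 1 fell (Nes -0.76, adjusted p = 0.0483; not called with RLE scaling), or 1 up and 3 down adjusted over the list alone. edgeR called 0 of 11 trophectoderm genes (4 at an unadjusted p under 0.05, DESeq2 0; 0 adjusted over the list alone), the nearest being Rhox6 (-0.43, adjusted p = 0.0777). Of 12 fibroblast genes 1 rose (the matrix gene Postn, at 0.0901 and 0.0716 CPM in WT and 1.61 and 1.43 CPM in MCM2_2A) and 2 fell (Tagln and Acta2), or 3 and 2 adjusted over the list alone. Camera called none of these 5 lists (adjusted p = 0.976, 0.278, 0.530, 0.0647 and 0.204). The endoderm test pointed down with a median of -0.051 and a mean of 0.014, and the neuroectoderm test down with a median of -0.088 and a mean of 0.003. When any one of the MCM2_2A or POLA1_hbm replicates was left out, the endoderm, mesoderm and neuroectoderm lists held 0 calls (adjusted p 0.0705 to 0.334 for the genes named) and the fibroblast list 1. Bmp4 (0.0651), Kdr (0.0896) and Nes (0.113) were not called without WT replicate 1. The mesoderm list then held 1 call, and without WT replicate 2 the mesoderm, neuroectoderm, trophectoderm and fibroblast lists held 8, 6, 3 and 5.

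Replication-dependent histone genes were the list with most calls in MCM2_2A: 0 of 69 rose and 23 fell (55 adjusted over the list alone; median -0.321; camera adjusted p = 2.34e-29, and adjusted p = 0.469 with an estimated correlation). Hist3h2ba fell by 1.33 ± 0.12 on the log2 scale, from 75.3 and 68.5 to 28.2 and 28.9 CPM. Hist3h2a (-0.86 ± 0.09) and the linker histone gene Hist1h1e (-0.81 ± 0.09) were called in each of those refits as well. Histone genes have many near copies and mostly RNA without a poly(A) tail. In any comparison single-gene counts depend on how shared reads were assigned. Without MCM2_2A replicate 1 or replicate 2 the list held 3 calls each time, without either POLA1_hbm replicate 21 or 22, and without WT replicate 2 it held 33. Of 42 replisome and nucleosome assembly genes 1 fell, Mcm2, and 0 rose (2 up and 1 down adjusted over the list alone; camera adjusted p = 0.206); without WT replicate 2 this list held 12 calls. Of 31 genes of H3K9 methylation and retroviral silencing 1 rose (Uhrf1 0.41) and 2 fell (Pphln1 -0.49, Rlim -0.63), or 3 and 3 adjusted over the list alone (camera adjusted p = 0.954, upward with a median of -0.013). That list held 0 calls without MCM2_2A replicate 1 or 2 (Pphln1, Rlim and Uhrf1 at adjusted p 0.126 to 0.291), 1 without either POLA1_hbm replicate and 9 without WT replicate 2. Uhrf1 was not called without WT replicate 1 (0.0941), and the replisome list held 0 calls without MCM2_2A replicate 1.

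Among the other lists in MCM2_2A, 4 of 32 imprinted genes fell (Rian -0.53, Snrpn -0.40, Peg12 -1.04, Phlda2 -0.51), or 6 adjusted over the list alone (camera adjusted p = 0.00271 downward, and adjusted p = 0.469 with an estimated correlation). Of 21 cholesterol synthesis genes 3 fell (Cyp51 -0.41, Nsdhl -0.54, Sc5d -0.40), also 3 adjusted over the list alone (camera adjusted p = 0.00271, and adjusted p = 0.713 with an estimated correlation). Of 20 glycolysis genes 1 fell (the glucose transporter Slc2a3, -0.52; 2 adjusted over the list alone; camera adjusted p = 0.238). Of 25 p53 targets 2 rose (Ephx1 0.76, Gtse1 0.29; 2 adjusted over the list alone; camera adjusted p = 0.0847). Of 18 interferon-response genes 1 rose (Xaf1 1.71 ± 0.21; 1 up and 1 down adjusted over the list alone; camera adjusted p = 0.0736), and it lost its call without MCM2_2A replicate 2 (0.0645). edgeR called 0 of 81 ribosomal protein genes (0 unadjusted, DESeq2 0, 0 adjusted over the list alone; camera adjusted p = 0.440; Rpl10 -0.13), and 0 of 3 tested Y-linked genes (0 unadjusted, DESeq2 0, 0 adjusted over the list alone; camera adjusted p = 0.530, upward with a median of -0.349). With MCM2_2A replicate 1, MCM2_2A replicate 2, POLA1_hbm replicate 1 or POLA1_hbm replicate 2 left out, the cholesterol, glycolysis and p53 lists held 0 calls (adjusted p 0.0538 to 0.367 for the genes named) and the imprinted list 1, 3, 1 and 2. Rian, Snrpn, Peg12 and Phlda2 were not called without either MCM2_2A replicate (0.131 to 0.33). Without WT replicate 1 the p53, interferon, imprinted, glycolysis and cholesterol lists held 10, 2, 2, 0 and 2 calls, and without WT replicate 2 they held 7, 6, 13, 3 and 5 and the Y-linked list 3.

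Repeat RNA in MCM2_2A was called higher for 19 of 854 subfamilies and lower for 0 by edgeR (104 in either direction at an unadjusted p under 0.05; DESeq2 29 higher and 2 lower). The endogenous retrovirus MMERGLN-int rose by 2.89 ± 0.28, from 50.1 and 58.6 to 259 and 546 CPM (adjusted p = 0.00197), and RLTR45-int rose by 1.88 ± 0.22. The major satellite GSAT_MM rose by 2.66 ± 0.37, from 0.541 and 1.72 to 7.80 and 6.91 CPM. That call was lost without MCM2_2A replicate 1 (0.0686), MCM2_2A replicate 2 (0.0684), POLA1_hbm replicate 1 (0.0524) or POLA1_hbm replicate 2 (0.0505). MMERGLN_LTR (2.21 ± 0.29) lost its call without POLA1_hbm replicate 1 (0.052), and RLTR1B (1.22 ± 0.15) without MCM2_2A replicate 2 (0.0761). Called higher by group were 7 of 261 ERVK, 5 of 87 ERV1, 4 of 84 ERVL-MaLR, 3 of 75 GLN, 3 of 27 MuLV-like, 2 of 8 MERVL (MERVL-int 0.73, MT2_Mm 0.79), 2 of 71 ERVL, 1 of 10 ETn/MusD (ETnERV2-int 0.75), 1 of 4 VL30 (MMVL30-int 0.58) and 1 of 4 satellite subfamilies. In the other 10 groups, IAP (24 tested), MMERVK10C (11), L1Md (6), L1 (121), L2 (4), Alu/B1 (16), B2 (5), B4 (4), MIR (4) and DNA transposons (147), edgeR called 0, with 0 to 12 per group at an unadjusted p under 0.05 and 0 to 3 by DESeq2. Camera called 14 of the 20 groups upward, ERVK at adjusted p = 2.65e-07 and GLN at adjusted p = 1.37e-05, and 0 of them with an estimated correlation. The lowest was adjusted p = 0.507 with an estimated correlation. Calls numbered 5 and 3 without MCM2_2A replicate 1 and 2, 10 and 13 without POLA1_hbm replicate 1 and 2, and 44 without WT replicate 2. The group counts moved with them: ERVK had 1 call without either MCM2_2A replicate and 18 without WT replicate 2, and VL30 had 0 without either MCM2_2A replicate. How multi-mapped reads were counted is not stated, so a subfamily's count is a sum over copies, some of them inside transcribed genes.

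In total edgeR called 447 of 18756 genes higher and 544 lower in MCM2_2A than in WT, including 409 and 530 of 14587 protein-coding genes (DESeq2 528 and 827 genes). Single libraries moved the total of 991: 787 without WT replicate 1, 3612 without WT replicate 2, 86 and 49 without MCM2_2A replicate 1 and 2, and 198 and 216 without POLA1_hbm replicate 1 and 2. Leaving out WT replicate 2 kept 985 of the 1010 called features, and leaving out MCM2_2A replicate 2 kept 49. The fit to the 4 compared libraries alone called 113 genes. POLA1_hbm libraries enter this comparison through the shared fit alone, and each library left out lowers the residual degrees of freedom. No called feature that was still tested changed sign in any of these refits. A lost call therefore does not by itself show that an effect rests on the library left out.

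**Figure D1:**
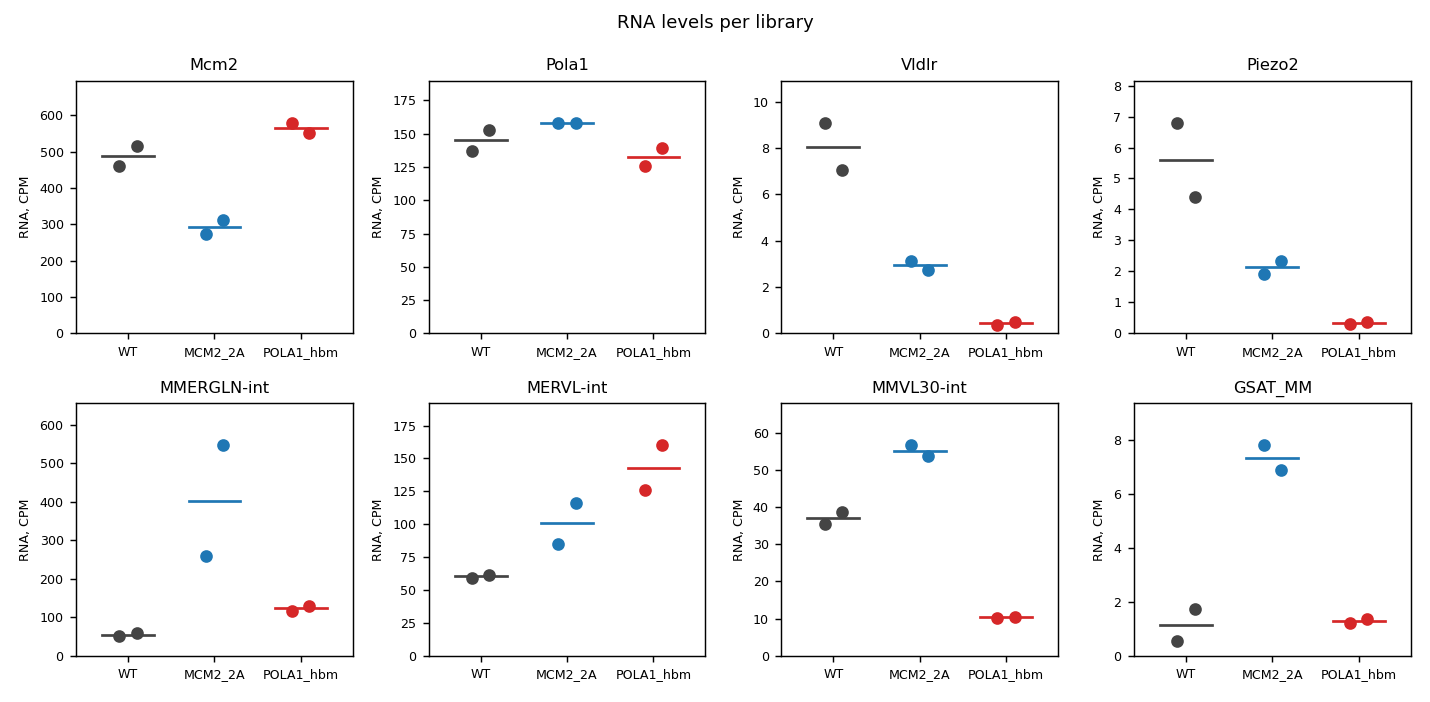
RNA level in CPM (vertical axes) of Mcm2, Pola1, Vldlr, Piezo2, MMERGLN-int, MERVL-int, MMVL30-int and GSAT_MM in each library (points) with group means (lines) for WT, MCM2_2A and POLA1_hbm. Mcm2 stood at 273 and 312 CPM in the MCM2_2A libraries against 462 and 517 in WT, and MMVL30-int at 10.2 and 10.3 CPM in the POLA1_hbm libraries against 35.4 and 38.6 in WT.

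POLA1_hbm against WT RNA asks which genes change when POLA1 carries its histone-binding mutation. Vldlr (ENSMUSG00000024924, chromosome 19: 27216484 to 27254231), a lipoprotein receptor gene, fell by 4.22 ± 0.25 on the log2 scale (SE, n = 2 libraries per genotype), from 9.07 and 7.04 to 0.366 and 0.487 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 5.95e-06). The mechanosensitive channel gene Piezo2 (ENSMUSG00000041482, chromosome 18: 63010213 to 63387183) fell by 4.05 ± 0.32, from 6.79 and 4.39 to 0.293 and 0.371 CPM (adjusted p = 4.43e-05). The acetyltransferase gene Acat3 (ENSMUSG00000062480, chromosome 17: 12923813 to 12940600) fell by 5.00 ± 0.37, from 3.27 and 3.05 to 0.147 and 0.0464 CPM. The activin subunit gene Inhbb (ENSMUSG00000037035, chromosome 1: 119415465 to 119422248) rose by 2.26 ± 0.20, from 7.21 and 12.3 to 46.9 and 47.0 CPM (adjusted p = 9.64e-05). Mcm2 (0.21 ± 0.09, adjusted p = 0.113) and Pola1 (-0.13 ± 0.08, adjusted p = 0.256) were not called.

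The motor protein gene Myo1f rose by 2.37 ± 0.22, Lrrn2 by 2.30 ± 0.24, Apol6 by 2.29 ± 0.32, Fkbp6 by 2.41 and Serpina3m by 3.50 ± 0.47. Rnu1b6, one of several U1 snRNA genes, rose by 4.86 ± 0.72 from 0.33 and 0 CPM to 6.13 and 2.71 CPM. Mir6236 fell by 4.21 ± 0.17, from 202 and 165 to 8.23 and 11.6 CPM. The mesoderm regulator T was called at -3.99 ± 0.46. The imprinted Nnat was called at -4.54 ± 1.32, but not without POLA1_hbm replicate 1 (-5.46, adjusted p = 0.165) or replicate 2 (-3.97, adjusted p = 0.214). The Y-linked Eif2s3y, Uba1y, Ddx3y and Uty were called lower, but WT replicate 1 was as low as the mutant: Ddx3y stood at 0 and 96.0 CPM in the WT libraries and at 0.0733 and 0 CPM in POLA1_hbm. Their calls were lost without WT replicate 2 or either POLA1_hbm replicate (adjusted p 0.157 to 0.914).

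In POLA1_hbm, 11 of 22 naive pluripotency genes rose and 2 fell (13 and 2 adjusted over the list alone): Tbx3 1.05 ± 0.12, Prdm14 0.97 ± 0.12, Nanog 0.63 ± 0.08 (268 and 292 to 456 and 412 CPM) and Fgf4 0.62 ± 0.08. The list passed camera at adjusted p = 4.58e-05, and had adjusted p = 0.639 with an estimated correlation. Of 19 formative and primed genes 3 rose and 9 fell, with the same numbers adjusted over the list alone: Fgf5 fell by 3.71 ± 0.26 (7.15 and 9.78 to 0.782 and 0.51 CPM), Pou3f1 by 1.49 ± 0.09, Fgf8 by 3.19 ± 0.39 and Sall2 by 1.19 ± 0.12 (camera adjusted p = 0.00190, and adjusted p = 0.599 with an estimated correlation). Of 13 genes of the 2-cell-like state 9 rose and 0 fell, all 9 also adjusted over the list alone, among them the multi-copy Zscan4a (1.53 ± 0.23) and Usp17lb (1.88 ± 0.35) (camera adjusted p = 9.12e-05, and adjusted p = 0.537 with an estimated correlation). Of 24 germline genes 7 rose and 4 fell (9 and 6 adjusted over the list alone), with Hormad1 (1.61 ± 0.16), Dazl (1.24 ± 0.17) and Tuba3a (1.60 ± 0.24) up. The piRNA-pathway gene Tdrd1 was down (-1.19 ± 0.17), and the list as a whole up (camera adjusted p = 0.0250, and adjusted p = 0.537 with an estimated correlation). These named genes kept their calls with DESeq2, RLE scaling, no filter, the compared libraries alone and each library left out. Without POLA1_hbm replicate 1 the formative, 2-cell-like and germline lists held 7, 2 and 5 calls, without POLA1_hbm replicate 2 the 2-cell-like and germline lists 3 and 6, without either MCM2_2A replicate or WT replicate 1 the 2-cell-like list 5, and without WT replicate 2 the germline list 18.

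Among lineage lists in POLA1_hbm, 1 of 21 endoderm genes rose and 10 fell (2 and 11 adjusted over the list alone), with the epithelial keratins Krt8 (-2.85 ± 0.36), Krt18 (-2.83) and Krt19 (-1.46) down (camera adjusted p = 0.0196, and adjusted p = 0.639 with an estimated correlation). Of 12 fibroblast genes 0 rose and 8 fell, also 8 adjusted over the list alone. Tagln was at -3.35 ± 0.44 (list camera adjusted p = 0.00424, and adjusted p = 0.537 with an estimated correlation). Acta2 (-2.83) lost its call without POLA1_hbm replicate 1 (0.0947) or 2 (0.0751), and Col1a2 (-1.10) without POLA1_hbm replicate 2 (0.0886). Of 17 mesoderm genes 3 rose and 5 fell, with the same numbers adjusted over the list alone: Wnt3 (-1.94) and T down, Bmp4 (0.75) up (camera adjusted p = 0.423). Of 13 neuroectoderm genes 2 rose and 3 fell (3 and 4 adjusted over the list alone), Nes at -1.91 ± 0.19 (camera adjusted p = 0.587, downward with a median of 0.183 and a mean of -0.45). Of 11 trophectoderm genes 1 rose (Tfap2c 0.64) and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.202), with Peg10 (-1.96) and Cdx2 (-1.98) losing their calls without POLA1_hbm replicate 1 (0.0537 and 0.0684). Without POLA1_hbm replicate 1 the endoderm, fibroblast, mesoderm, neuroectoderm and trophectoderm lists held 6, 2, 5, 1 and 1 calls, and without POLA1_hbm replicate 2 7, 2, 6, 2 and 3.

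Glycolysis genes were lower as a group in POLA1_hbm: 15 of 20 fell and 0 rose (16 and 0 adjusted over the list alone; camera adjusted p = 5.39e-08, and adjusted p = 0.537 with an estimated correlation; fry adjusted p = 0.0303). The lactate transporter gene Slc16a3 fell by 0.79 ± 0.07, Aldoc by 1.14, Tpi1 by 0.67 and Pfkl by 0.58. Of 21 cholesterol synthesis genes 1 rose and 7 fell, the same adjusted over the list alone (Msmo1 -0.68, Cyp51 -0.44, Hmgcs1 -0.37; camera adjusted p = 0.0426, and adjusted p = 0.639 with an estimated correlation). Of 69 replication-dependent histone genes 3 rose and 30 fell (4 and 34 adjusted over the list alone; camera adjusted p = 8.79e-06, and adjusted p = 0.639 with an estimated correlation). Hist2h3c1 fell by 2.27 ± 0.11, with Hist3h2ba (-1.24), Hist1h2br (-1.14) and Hist2h2aa1 (-0.98). All rest on how shared reads were assigned. Of 42 replisome and nucleosome assembly genes 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 0.00619, and adjusted p = 0.639 with an estimated correlation). Tonsl, which binds histones on new DNA, rose by 0.63 ± 0.09, while Rpa2 (0.51), Asf1b (0.49) and Pole3 (0.52) lost their calls without POLA1_hbm replicate 1 (0.0649, 0.0639 and 0.0711). Of 31 genes of H3K9 methylation and retroviral silencing 7 rose and 6 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.181). The zinc-finger repressor genes Zfp809 (0.81 ± 0.09) and Zfp57 (0.93 ± 0.12) were up and Pphln1 (-0.69) and Rlim (-0.77) down. Without POLA1_hbm replicate 1 the cholesterol, replisome and H3K9 lists held 4, 1 and 8 calls and without POLA1_hbm replicate 2 the cholesterol, histone and H3K9 lists 4, 19 and 8. The cholesterol and replisome lists held 5 and 7 calls without either MCM2_2A replicate, and the replisome list 18 without WT replicate 2.

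Among the other lists in POLA1_hbm, 1 of 32 imprinted genes rose and 12 fell (1 and 13 adjusted over the list alone), Magel2 at -2.06 ± 0.31, Dlk1 at -1.15 and Snrpn at -0.50 (camera adjusted p = 0.00424, and adjusted p = 0.537 with an estimated correlation). Of 18 interferon-response genes 3 rose and 8 fell, the same adjusted over the list alone (camera adjusted p = 0.497). Xaf1 (1.70 ± 0.21), Oas1a (1.15) and Irf9 (0.75) were up and Bst2 (-0.91) was down, the last not without POLA1_hbm replicate 2 (0.0569). Of 81 ribosomal protein genes 13 rose and 2 fell (8 and 2 adjusted over the list alone), such as Rpl34 at 0.41 ± 0.08 (camera adjusted p = 0.00424, and adjusted p = 0.693 with an estimated correlation). Of 25 p53 targets 2 rose (Ephx1 0.84, Gtse1 0.37) and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.929, upward with a median of -0.03 and a mean of -0.143), and Pmaip1 (-1.35) lost its call without POLA1_hbm replicate 1 (0.051) or 2 (0.0593). All 3 tested Y-linked genes were called lower, also adjusted over the list alone (camera adjusted p = 0.249), and 0 of them without WT replicate 2, POLA1_hbm replicate 1 or POLA1_hbm replicate 2. Without POLA1_hbm replicate 1 the imprinted, interferon, ribosomal and p53 lists held 5, 6, 3 and 2 calls, without POLA1_hbm replicate 2 5, 4, 27 and 2, and without WT replicate 1 and WT replicate 2 the p53 list held 11 and 13. The ribosomal list held 5 and 6 calls without MCM2_2A replicate 1 and 2.

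Repeat RNA in POLA1_hbm was called higher for 72 and lower for 26 of 854 subfamilies (DESeq2 65 and 23). MERVL-int rose by 1.24 ± 0.15, from 59.4 and 61.7 to 126 and 160 CPM (adjusted p = 0.000625), with its LTR MT2_Mm (1.19 ± 0.13), RLTR45-int (1.48 ± 0.21), RLTR9D2 (1.45 ± 0.23) and MTEb-int (1.19 ± 0.22). MMVL30-int fell by 1.85 ± 0.09, from 35.4 and 38.6 to 10.2 and 10.3 CPM (adjusted p = 1.99e-06). LTRIS4B fell by 4.15 ± 0.27, RLTR1D by 2.49 ± 0.15, RLTR44C by 2.29 ± 0.25 and Lx5b by 1.65 ± 0.12. Called higher and lower by group were ERVK 26 and 5, ERV1 6 and 6, GLN 12 and 3, ERVL-MaLR 12 and 0, ERVL 8 and 0, L1 7 and 13, Alu/B1 5 and 0, B2 3 and 0, DNA transposons 3 and 1, MERVL 2 and 0, VL30 0 and 2, IAP 0 and 2, ETn/MusD 1 and 0, MMERVK10C 1 and 0, MuLV-like 1 and 1, and L1Md 1 and 1. edgeR called 0 satellite, L2, B4 and MIR subfamilies (0 to 3 per group at an unadjusted p under 0.05, DESeq2 0). Camera called 7 groups upward, such as Alu/B1 (adjusted p = 0.00267) and MERVL (adjusted p = 0.00866), and VL30 downward (adjusted p = 0.0186; fry adjusted p = 0.0320). None of the 20 groups was called with an estimated correlation, the lowest being adjusted p = 0.769 with an estimated correlation. Repeat calls depended on the POLA1_hbm replicates: 120 higher and 11 lower without replicate 1 and 16 and 30 without replicate 2, Alu/B1 15 and 1 higher, ERVL-MaLR 18 and 1. Repeats took 4.05% of counts in POLA1_hbm replicate 1 and 5.21% in replicate 2. Without either MCM2_2A replicate 51 repeats were called.

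edgeR called 2332 of 18756 genes higher and 3022 lower in POLA1_hbm than in WT (7794 at an unadjusted p under 0.05; DESeq2 2034 and 2520). Of 14587 protein-coding genes, 2045 rose and 2365 fell, and of 1963 processed pseudogenes, 42 rose and 534 fell. The total of 5354 became 2030 without POLA1_hbm replicate 1 and 2346 without POLA1_hbm replicate 2, and was 3643 to 6823 without any other library. The file numbers set the POLA1_hbm RNA libraries apart from the WT and MCM2_2A ones, so a batch and the genotype cannot be told apart.

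**Figure D2:**
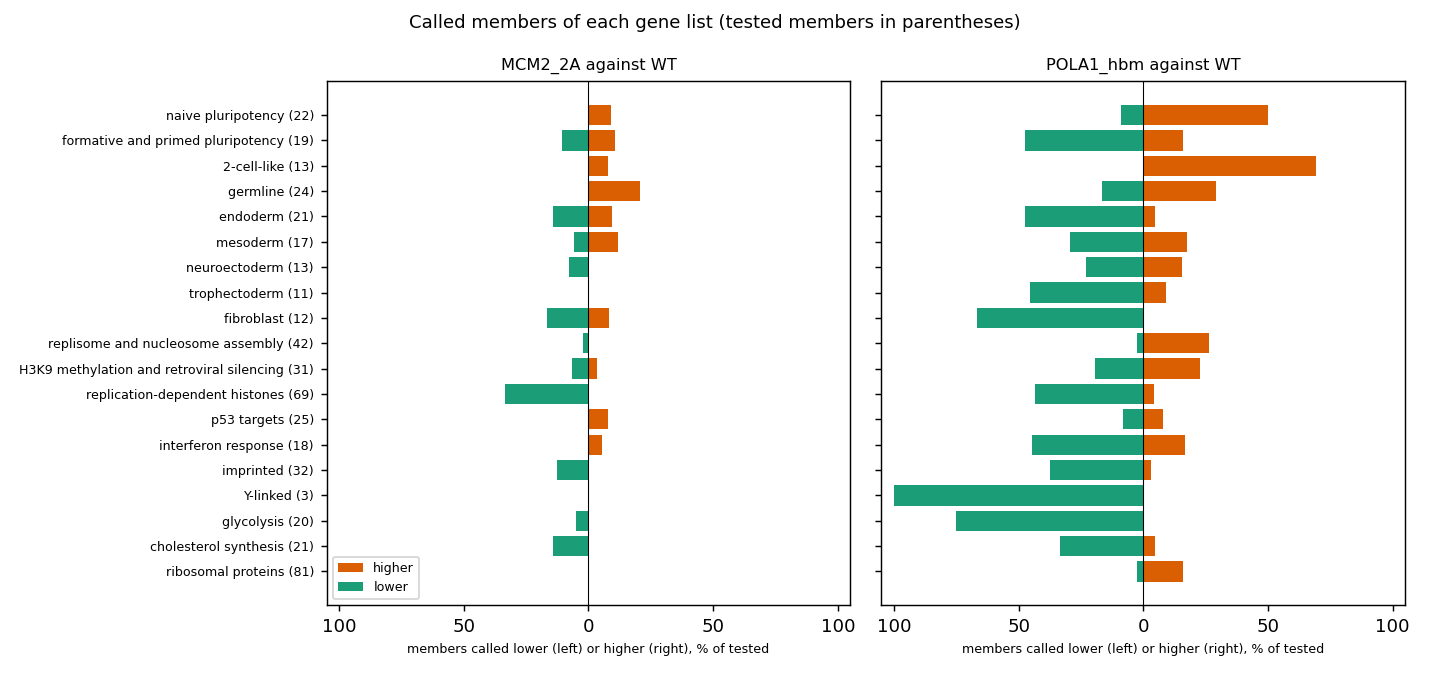
Percent of tested members of each gene list (vertical axis) called lower or higher (horizontal axis, bars) in MCM2_2A and POLA1_hbm against WT. Glycolysis showed 15 of 20 genes lower in POLA1_hbm against 1 of 20 in MCM2_2A, and the histone list 30 and 23 of 69 lower.

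POLA1_hbm against MCM2_2A RNA compares the mutants directly. File numbers set the POLA1_hbm libraries apart from the MCM2_2A ones, so a batch and the genotype cannot be told apart here either. The securin gene Pttg1 (ENSMUSG00000020415, chromosome 11: 43420250 to 43426251) was higher in POLA1_hbm by 2.03 ± 0.16 (SE, n = 2 libraries per genotype), at 26.7 and 23.4 CPM against 5.95 and 6.30 in MCM2_2A (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 6.54e-05). Mcm2 was higher by 0.95 ± 0.09 (adjusted p = 0.000198), and Pola1 was not called (-0.26 ± 0.08, adjusted p = 0.0557). Yam1, a long noncoding RNA gene, was higher by 1.88 ± 0.14 (94.8 and 99.6 CPM against 26.0 and 26.7 in MCM2_2A, adjusted p = 3.38e-05), as was Lrrn2 (1.84 ± 0.23). Acat3 was lower in POLA1_hbm by a log2 fold change of -5.02 ± 0.37 and Mir6236 by -4.58 ± 0.17. Rnu1b6 (1.92 ± 0.53) was not called by DESeq2 (0.46) or without any one of the MCM2_2A and POLA1_hbm replicates (0.0669 to 0.303), and Nnat (-6.08 ± 1.25) was not called without POLA1_hbm replicate 1 (0.131) or 2 (0.129). Eif2s3y and Uba1y were also called lower: Eif2s3y stood at 65.1 and 13.2 CPM in MCM2_2A and at 0.0244 and 0 CPM in POLA1_hbm.

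Between the mutants, 6 of 22 naive pluripotency genes were higher in POLA1_hbm and 3 lower (10 and 3 adjusted over the list alone; camera adjusted p = 0.0359, and adjusted p = 0.919 with an estimated correlation). Of 19 formative and primed genes 0 were higher and 9 lower (2 and 11 adjusted over the list alone; camera adjusted p = 0.000116, and adjusted p = 0.512 with an estimated correlation): Fgf5 -3.50 ± 0.26, Pou3f1 -1.29 ± 0.09, Dusp6 -0.95 ± 0.13 and Sall2 -0.82. The 2-cell-like list had 1 of 13 higher (Zscan4a 0.86, not by DESeq2 at 0.0615; 1 adjusted over the list alone; camera adjusted p = 0.359). Of 24 germline genes 2 were higher and 4 lower (3 and 5 adjusted over the list alone; camera adjusted p = 0.958), with Hormad1 1.32 ± 0.16 and Brdt -2.17 ± 0.31. Of 21 endoderm genes 0 were higher and 7 lower (0 and 10 adjusted over the list alone; camera adjusted p = 0.0107, and adjusted p = 0.804 with an estimated correlation). Of 17 mesoderm genes 1 was higher and 5 lower, the same adjusted over the list alone (camera adjusted p = 0.0709; fry adjusted p = 0.0381), with Eomes -1.19 ± 0.17. Of 13 neuroectoderm genes 3 were higher and 3 lower (4 and 4 adjusted over the list alone; Stmn2 0.59 ± 0.08), and of 11 trophectoderm genes 2 and 2, the same adjusted over the list alone (Tfap2c 0.91 ± 0.09), both with camera adjusted p = 0.958. Of 12 fibroblast genes 0 were higher and 7 lower (0 and 8 adjusted over the list alone; camera adjusted p = 3.45e-05, and adjusted p = 0.512 with an estimated correlation; fry adjusted p = 0.0381), Col1a2 at -1.90 ± 0.25. The naive, formative, endoderm and 2-cell-like lists held 16, 12, 15 and 2 calls without WT replicate 1 and 16, 14, 14 and 2 without WT replicate 2. The 9 lists held 0 to 6 calls each without MCM2_2A replicate 1, MCM2_2A replicate 2, POLA1_hbm replicate 1 or POLA1_hbm replicate 2 (Zscan4a 0.101 to 0.221).

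Of 20 glycolysis genes 0 were higher and 11 lower in POLA1_hbm than in MCM2_2A (0 and 13 adjusted over the list alone; camera adjusted p = 2.82e-07, and adjusted p = 0.512 with an estimated correlation; fry adjusted p = 0.0381), Aldoc -1.09, Slc16a3 -0.73 ± 0.07, Pgk1 -0.70 and Pfkl -0.57. Of 69 histone genes 14 were higher and 7 lower (16 and 8 adjusted over the list alone; camera adjusted p = 0.0298 upward, and adjusted p = 0.919 with an estimated correlation), with Hist1h2bq (1.13 ± 0.11) and Hist2h3c2 (1.13 ± 0.13) higher and Hist2h3c1 (-2.01 ± 0.11) lower. Of 81 ribosomal protein genes 14 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.000116, and adjusted p = 0.919 with an estimated correlation). Of 18 interferon-response genes 2 were higher and 7 lower, the same adjusted over the list alone (camera adjusted p = 0.0406, and adjusted p = 0.512 with an estimated correlation; fry adjusted p = 0.0381), Oasl2 at -2.06 ± 0.28. Replisome genes were 6 higher and 0 lower of 42 (4 and 0 adjusted over the list alone; camera adjusted p = 0.0521), H3K9 methylation and silencing genes 7 and 3 of 31 (7 and 4; 0.154), p53 targets 0 and 2 of 25 (0 and 2; 0.257), imprinted genes 2 and 5 of 32 (2 and 6; 0.372), cholesterol synthesis genes 1 and 3 of 21 (2 and 3; 0.958) and Y-linked genes 0 and 1 of 3 (0 and 3; 0.0597). Leaving out MCM2_2A replicate 1, MCM2_2A replicate 2, POLA1_hbm replicate 1 or POLA1_hbm replicate 2 gave 5, 5, 7 and 7 glycolysis calls, 10, 8, 11 and 27 histone calls, 0, 0, 2 and 18 ribosomal calls and 3, 2, 1 and 2 interferon calls. The imprinted list then had 3, 7, 3 and 0 calls, the replisome list 1, 1, 1 and 5, the H3K9 list 0, 1, 3 and 5, and the p53, cholesterol and Y-linked lists 0 or 1. Without WT replicate 1 and WT replicate 2 the replisome list held 11 and 13 calls, the p53 list 7 and 8, the cholesterol list 7 and 5 and the Y-linked list 3 and 3.

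Repeats between the mutants were called higher in POLA1_hbm for 11 and lower for 47 of 854 (DESeq2 13 and 43). RLTR9F was higher by 1.07 ± 0.10. RLTR9D2 (1.01) and MTEb-int (0.93) were too, but not without any one of the MCM2_2A or POLA1_hbm replicates (0.0657 to 0.212). LTRIS4B (-4.63 ± 0.26), RLTR1D (-2.56 ± 0.15), MMVL30-int (-2.42 ± 0.09) and GSAT_MM (-2.52 ± 0.36) were lower, the last not without POLA1_hbm replicate 1 (-2.42, adjusted p = 0.0669). Higher and lower by group were IAP 1 and 5, ETn/MusD 1 and 0, MERVL 1 and 0, MMERVK10C 0 and 2, MuLV-like 0 and 4, VL30 0 and 2, GLN 1 and 8, L1Md 0 and 1, satellite 0 and 1, ERVK 5 and 16, ERV1 0 and 10, ERVL 2 and 1, ERVL-MaLR 1 and 0, L1 2 and 17, and DNA transposons 1 and 1. edgeR called 0 in L2, Alu/B1, B2, B4 and MIR (0 unadjusted, DESeq2 0). Camera called VL30 alone of 20 groups (adjusted p = 0.000156, and adjusted p = 0.836 with an estimated correlation; fry adjusted p = 0.0112). Repeat calls numbered 22 and 21 without MCM2_2A replicate 1 and 2, and 96 without WT replicate 1. Without POLA1_hbm replicate 1 31 were higher and 14 lower, and without POLA1_hbm replicate 2 4 and 42.

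In total 1486 genes were higher and 1857 lower in POLA1_hbm than in MCM2_2A, including 1345 and 1250 protein-coding genes and 17 and 494 processed pseudogenes (DESeq2 1475 and 1500 genes). The count was 768 and 622 without MCM2_2A replicate 1 and 2, 740 and 1132 without POLA1_hbm replicate 1 and 2, and 5581 and 5494 without WT replicate 1 and 2.

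Effects shared by the mutants were asked for over all tested genes, since both are compared with the same 2 WT libraries and would correlate for that reason alone. Both mutants called 259 genes higher and 372 lower, where independent calls would give 55.6 and 87.7. Data simulated with shared WT libraries and no mutant effects gave means of 0.33 and 0.19, but held only 1.05 to 1.44 calls per mutant and direction. They therefore do not show how far shared controls add to the overlap of many calls. Tbx3, Xaf1 and Serpina3m were among those higher in both, and Krt8, Tagln and Hist3h2ba among those lower in both. The MCM2_2A calls of Krt8 and Tagln were lost without any one of the MCM2_2A or POLA1_hbm replicates, and that of Xaf1 without MCM2_2A replicate 2. Most MCM2_2A calls, on which the overlap rests, were lost without either MCM2_2A replicate. The Pearson correlation across genes was 0.415, below the 0.502 ± 0.0118 (mean and SD, 100 draws) of these simulated data. The Spearman correlation was above its simulated value, 0.485 against 0.459 ± 0.00671, and the covariance was 0.192 against 0.0499. For protein-coding genes r was 0.525 against 0.502 and the Spearman value 0.565 against 0.461, with a covariance of 0.194 against 0.0362. For repeats r was 0.343 against 0.493 and the Spearman value 0.407 against 0.457, with a covariance of 0.0592 against 0.0577, and 13 repeats were higher in both against 1.60 from independent calls. The simulation gave all libraries the same spread for a feature. In the data WT replicates differed more (root mean square log2 difference of 0.511) than MCM2_2A (0.35) or POLA1_hbm replicates (0.405). A wider WT spread raises the correlation and covariance that shared controls alone give, so values above the simulated ones do not establish shared effects. Without WT replicate 2 r was 0.595 for genes and 0.567 for repeats. With each mutant set against a different WT library, a division chosen after seeing the data that leaves 1 control library for each, r was 0.139 and 0.217 for genes and 0.067 and 0.027 for repeats. Genes are not independent replicates, and both the smaller number of controls and a difference between the WT libraries can lower these values.

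**Figure D3:**
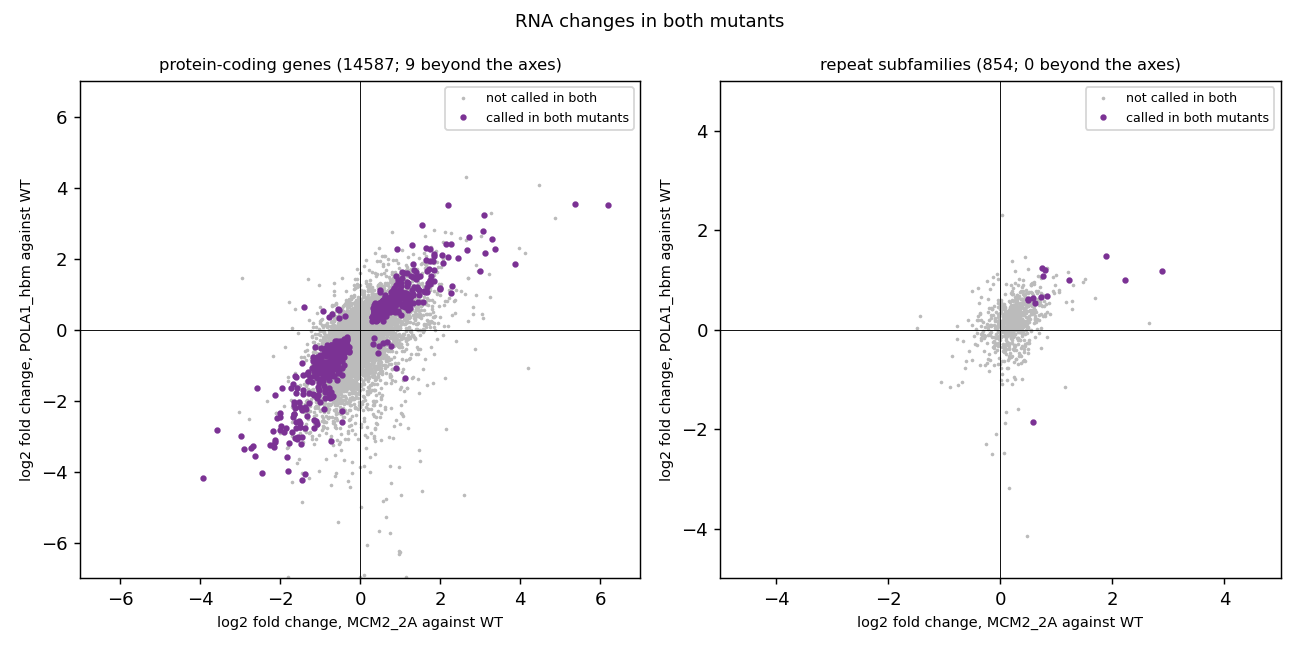
Log2 fold change in MCM2_2A (horizontal axis) against that in POLA1_hbm (vertical axis), both relative to WT, for 14587 protein-coding genes (9 of them beyond the axes) and 854 repeats, 1 point each. The correlation was 0.525 for protein-coding genes and 0.343 for repeats.

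H3K9me3 in POLA1_hbm against WT asks whether this mark differs in the POLA1 mutant. The major satellite GSAT_MM, the repeat of pericentromeric heterochromatin, was lower by a log2 fold change of -0.55 ± 0.07 (SE, n = 2 libraries per genotype), at 54150 and 49590 CPM in WT and 35850 and 34820 CPM in POLA1_hbm (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 3.21e-10). DESeq2 gave -0.65 with an adjusted p of 0.999, and the fit to the 4 compared libraries -0.47 with an adjusted p of 0.0667. The retroviral IAPEz-int was called at -0.35 ± 0.07, with overlapping groups (88680 and 67100 against 69400 and 52490 CPM), and not without WT replicate 1 (0.0714) or POLA1_hbm replicate 2 (0.763), or with total-count scaling (0.117). The zinc-finger gene Zfp444 (ENSMUSG00000044876, chromosome 7: 6172226 to 6193811) was higher by 1.93 ± 0.38, from 2.42 and 2.03 to 7.55 and 10.1 CPM, but not without POLA1_hbm replicate 2 (0.0836).

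H3K9me3 over L1Md_F2 (-0.30) and L1MEh (-0.81) was also called lower in POLA1_hbm, L1Md_F2 not without POLA1_hbm replicate 1 (0.0572) or 2 (0.765), and L1MEh not without WT replicate 2 or either POLA1_hbm replicate (0.171 to 0.406). Of the predicted genes in the satellite region at the start of chromosome 9, Gm17535 (-0.61 ± 0.11) and Gm10720 (-0.60 ± 0.11) were lower. The mitochondrial mt-Nd1 was called at -0.60, with 333 and 353 CPM in WT and 333 and 117 in POLA1_hbm, and stood at -0.04 (adjusted p = 0.914) without POLA1_hbm replicate 2. By group 1 IAP, 1 L1Md, 1 satellite, 1 ERVK and 2 L1 subfamilies were lower, and in the other 15 groups edgeR called 0 (0 to 36 per group at an unadjusted p under 0.05, DESeq2 0). With total-count scaling the IAP, L1Md, ERVK and L1 groups had 0 calls. Camera called all 20 groups lower, and 0 with an estimated correlation (lowest adjusted p = 0.436 with an estimated correlation). On the TMM scale the median was -0.183 over all repeats and 0.286 over genes. That difference enters the camera test of every group, while edgeR called 4 repeats. Total-count scaling moved the median of all features from 0.146 to 0.353 in this comparison and from 0.039 to 0.291 in MCM22A against WT, so the directions of edgeR calls are relative to the TMM scale.

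In all 20 features were higher and 32 lower in H3K9me3 of POLA1_hbm by edgeR (812 unadjusted), 0 by DESeq2 and 0 in the fit to the compared libraries. With total-count scaling 66 were higher and 7 lower. The count was 90 without WT replicate 1, 103 without POLA1_hbm replicate 1 and 16 without POLA1_hbm replicate 2, and 31, 30, 13 and 2 repeats were called without WT replicate 1, WT replicate 2, POLA1_hbm replicate 1 and POLA1_hbm replicate 2. L1 calls were 21, 7, 3 and 0, ERVK calls 4, 14, 6 and 0, IAP calls 0, 9, 4 and 0 and satellite calls 2, 1, 1 and 2 in that order. None of the 14 named features kept its call in all refits run for named features, and DESeq2 called 0 of them.

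**Figure D4:**
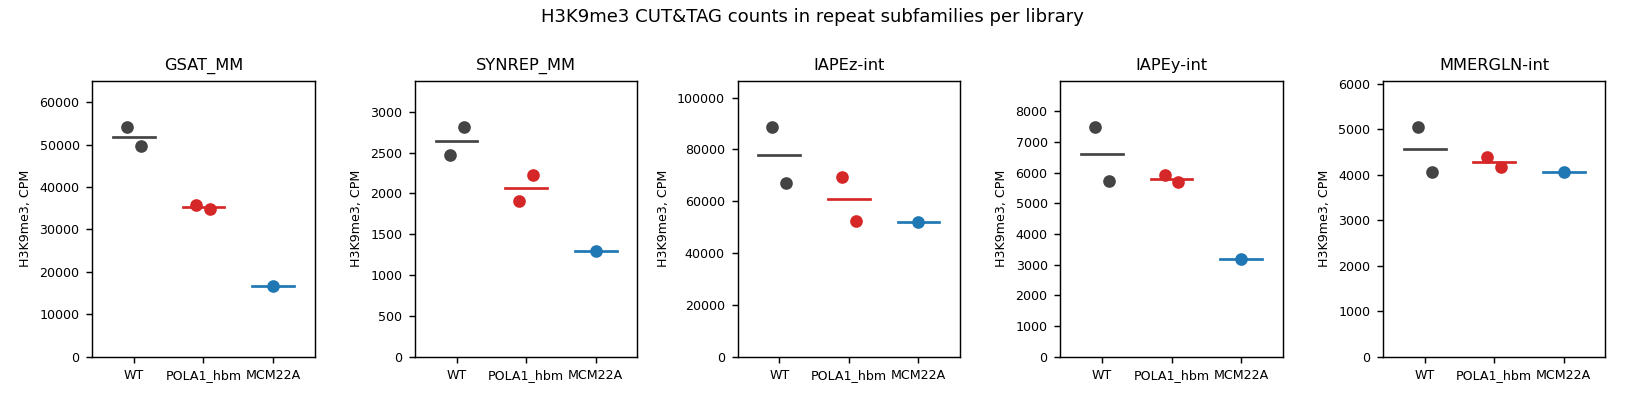
H3K9me3 signal in CPM (vertical axes) over GSAT_MM, SYNREP_MM, IAPEz-int, IAPEy-int and MMERGLN-int in each library (points) with group means (lines) for WT, POLA1_hbm and the single MCM22A library. GSAT_MM stood at 16740 CPM in MCM22A, 35850 and 34820 in POLA1_hbm and 54150 and 49590 in WT.

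H3K9me3 in MCM22A against WT asks the same of the MCM2 mutant, with 1 mutant library whose spread is borrowed from the other groups. GSAT_MM was lower by a log2 fold change of -1.63 ± 0.10 (SE, n = 1 and 2 libraries), at 16740 CPM (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 4.31e-59), and by -1.38 with total-count scaling. The related satellite SYNREP_MM was lower by -1.03 ± 0.13 (2464 and 2813 to 1296 CPM), IAPEy-int by -1.05 ± 0.12 (7485 and 5724 to 3188 CPM), RLTR5_Mm by -1.05 ± 0.15 and C573_MM by -1.05 ± 0.18. These repeats kept their calls with DESeq2, RLE and total-count scaling, no filter, the compared libraries alone and each WT or POLA1_hbm library left out, as did the predicted small RNA gene Gm23056 (-2.41 ± 0.42) where it was tested. IAPEy-int has copies on the Y chromosome, and reads counted in Y genes were also lower in the MCM22A library (760 against 1309 and 1038 per 1e+06). The genes called higher, Cndp2 (2.83), Zfp566 (2.24) and the predicted Gm47299 and Gm47305 (2.61), were not called without WT replicate 1 (adjusted p 0.117 to 0.531). Cndp2 (0.158), Gm47299 and Gm47305 (0.122) were not called without WT replicate 2 either, nor Zfp566 without POLA1_hbm replicate 1 (0.0552).

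H3K9me3 was lower in MCM22A over 9 of 25 IAP subfamilies (camera adjusted p = 1.63e-11), 18 of 278 ERVK (2.81e-06), 4 of 10 ETn/MusD (0.000645; fry adjusted p = 0.0488), 4 of 8 satellite (0.00192) and 6 of 120 ERV1 (0.00949). Camera called 9 groups lower at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.828 with an estimated correlation). The median was -0.061 over all repeats and 0.102 over genes, a difference that enters the camera test of every group. H3K9me3 was also lower over 2 of 131 L1, 2 of 6 L1Md, 1 of 11 MMERVK10C, 1 of 29 MuLV-like, 1 of 5 VL30 and 1 of 102 ERVL-MaLR subfamilies. In the other 9 groups edgeR called 0 (0 to 9 per group unadjusted, DESeq2 0). With total-count scaling the lower calls were 6 IAP, 6 ERVK, 3 satellite, 4 ERV1 and 0 ETn/MusD subfamilies, and 0 L1, L1Md, MMERVK10C, MuLV-like, VL30 and ERVL-MaLR subfamilies. Called higher on that scale were 6 ERVK, 2 satellite, 2 ERVL-MaLR, 2 B4, 1 MMERVK10C, 1 GLN, 1 L2 and 1 DNA transposon subfamilies. IAP had 18 lower calls without WT replicate 2 or either POLA1_hbm replicate, ERVK 36, 38 and 40, and ERV1 9, 9 and 11. L1 had 9 and 7 without WT replicate 1 and 2. Without WT replicate 2 L1Md had 6, MuLV-like 4, MMERVK10C 3, VL30 2, GLN 4 and Alu/B1 1, and without POLA1_hbm replicate 1 and 2 MuLV-like had 3 and 3, L1Md 1 and 1, GLN 3 and 4 and VL30 1 and 2. VL30 had 0 without WT replicate 1, where IAP had 12, ERVK 23, L1Md 3 and ERV1 4. With RLE scaling ERV1 had 4, L1 and L1Md 1 each, and MMERVK10C and VL30 0.

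In total edgeR called 22 features higher and 115 lower in MCM22A (699 unadjusted; DESeq2 0 and 21), and 0 repeats higher and 34 lower (103 unadjusted; DESeq2 0 and 8). Total-count scaling gave 69 and 71 features and 16 and 15 repeats, so the balance of directions depends on the scale. A term for the file-name tag left 38 features. Without WT replicate 2, POLA1_hbm replicate 1 and POLA1_hbm replicate 2, 61, 58 and 62 repeats were called.

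H3K9me3 in POLA1_hbm against MCM22A tests the difference between the mutants. GSAT_MM was higher in POLA1_hbm by 1.08 ± 0.09, RLTR5_Mm by 1.06 ± 0.15, MURVY-int by 0.99 ± 0.13 (1368 against 2639 and 2785 CPM) and IAPEy-int by 0.86 ± 0.12 (SE, n = 2 and 1 libraries; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). These kept their calls with DESeq2, RLE and total-count scaling, no filter, the compared libraries alone and each WT or POLA1_hbm library left out. MURVY-int and IAPEy-int have copies on the Y chromosome, whose genes had 1309 and 1484 reads per 1e+06 in POLA1_hbm against 760 in MCM22A. The predicted satellite-region gene Gm10718 was higher by 1.11 ± 0.14 (adjusted p = 6.29e-12). C573_MM (0.86) was not called without a filter (0.185) or in the fit to the compared libraries (0.0539), and Trpm8 (1.46 ± 0.29) and the centromere assembly gene Hjurp (1.14) not without POLA1_hbm replicate 2 (0.537 and 0.869). In all 31 features were higher and 0 lower (453 unadjusted; DESeq2 17), and 13 repeats higher and 0 lower (95 unadjusted; DESeq2 5): 4 IAP, 3 satellite, 5 ERVK and 4 ERV1 subfamilies. In the other 16 groups edgeR called 0 (0 to 15 per group unadjusted, DESeq2 0), while camera at the preset correlation called IAP upward (adjusted p = 0.00135) and 7 groups downward, against the direction of the calls. With an estimated correlation no group passed (lowest adjusted p = 0.848 with an estimated correlation). The median was -0.127 over all repeats and 0.18 over genes, a difference that enters the camera test of every group. Calls were 47 higher and 4 lower, 57 and 8, 45 and 30, and 82 and 0 features, 23, 37, 23 and 22 repeats (0, 5, 1 and 0 of them lower), 7, 7, 5 and 7 IAP, 11, 16, 9 and 10 ERVK and 5, 7, 6 and 4 ERV1 subfamilies without WT replicate 1, WT replicate 2, POLA1_hbm replicate 1 and POLA1_hbm replicate 2.

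Across 853 repeats tested in both assays, the question was whether those with less H3K9me3 had more RNA. In the MCM2 mutant the Pearson correlation of the log2 fold changes was -0.186 (permutation p = 1e-05, the smallest that 100000 permutations can give; adjusted p = 4e-05) and the Spearman correlation -0.112 (permutation p = 0.00091, adjusted p = 0.00182). The latter was -0.048 (permutation p = 0.155) without RNA WT replicate 2 and -0.05 (permutation p = 0.35) at a mean log2 CPM of at least 2 in both assays. In POLA1_hbm the values were -0.047 (permutation p = 0.167) and 0.057 (permutation p = 0.0956, adjusted p = 0.127), and the Spearman value was 0.092 (permutation p = 0.00548) without RNA WT replicate 2 and 0.146 (permutation p = 0.00607) at that minimum. The adjustment covers 4 tests, and repeat subfamilies share sequence and loci, so they are not independent replicates. MMERGLN-int, with the largest RNA rise of the named repeats in MCM2_2A, was not among the repeats named for lower H3K9me3.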

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

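The tests of library preparation through 7SK, of the Y chromosome and its parts, of mislabelling and of the enrichment of the MCM22A library were chosen only after the result was seen. So were a test of depth for the pseudogenes and of another mislabelling for the Y-linked genes, which argued against both explanations and were replaced by the 7SK and Y-absence tests.

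Effects of the mutants against WT that go in opposite directions were singled out where the difference between the mutants was itself called by edgeR. This applied to 21 genes and 1 repeat subfamily. The repeat, MMVL30-int, the internal part of a VL30 retrovirus, rose by 0.58 ± 0.09 in MCM2_2A and changed by -1.85 ± 0.09 in POLA1_hbm, a difference of -2.42 (log2, SE). Its call in MCM2_2A against WT was lost without MCM2_2A replicate 1 or replicate 2. So were most calls of that comparison, on which the 21 genes rest as well. A2m and Fam181b were near the threshold there (edgeR adjusted p = 0.0465 and 0.0439). Among the genes, chosen here after their values were seen, were the protease inhibitor gene A2m (1.12 in MCM2_2A and -1.37 in POLA1_hbm), Pttg1 (-1.39 and 0.64), Fam181b (0.90 and -1.08), Nlrp9b (-0.93 and 0.52), the cohesin gene Stag3 (-0.70 and 0.44), the metallothionein gene Mt1 (0.44 and -0.67), Fgf17 (-0.79 and 0.36), Fgfr2 (-0.53 and 0.33), Smad7 (0.33 and -0.40) and Kdm2b (0.34 and -0.24). No explanation was tested for these, and a batch of the POLA1_hbm libraries cannot be told apart from the genotype.

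Processed pseudogenes were called lower in POLA1_hbm RNA far more often than higher, 534 against 42 of 1963, and 127 of the 534 fell more than 8-fold against 89 of 2365 protein-coding genes called lower. Reads shared with coding genes would need the pseudogenes called lower to share more sequence with them, but they shared less: a median of 34.95% of 50-base words against 51.76% in the rest, a difference of -16.8 points (332 and 547 pseudogenes of at least 1 CPM, permutation p = 1e-05, the smallest the permutations can give). Reads with mismatches were not covered by that comparison, and lower depth is excluded by POLA1_hbm totals of 42871796 and 43375749 counts against 32900024 and 41966019 in WT. Less transcription of pseudogenes whatever their sequence stays open. Of those with under 10% shared words 54.55% were called lower (48 of 88, exact 95% interval 43.58 to 65.2) and of those with at least 50% shared words 29.57% (118 of 399, 25.14 to 34.32), against 16.49% of protein-coding genes. Both shares exceed that of coding genes, but they differ with shared sequence, and reads of coding genes counted to a pseudogene would hide part of a fall. Another preparation, alignment or counting of the POLA1_hbm libraries fits: the ratio of 7SK counted as a gene to 7SK counted as a repeat was 1.053 and 1.063 there and 0.900 to 0.921 in the other 4 libraries, a gap of 0.132, and as file numbers set these libraries apart, batch and genotype cannot be told apart.

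Y-linked RNA differed between replicates of a genotype: Ddx3y stood at 0 and 96.0 CPM in WT, 52.0 and 3.52 CPM in MCM2_2A and 0.0733 and 0 CPM in POLA1_hbm. Loss of the whole Y chromosome from the cells of WT replicate 1 and both POLA1_hbm libraries cannot be told apart from other causes in RNA alone: Ddx3y, Eif2s3y and Uty had at most 3 counts in each, as they would if silent. The POLA1_hbm H3K9me3 libraries do not settle it, and the labels do not say whether they came from the same cells. Their 1517 Y genes that start from position 2700000 up to the region shared with X had 1250 and 1440 reads per 1e+06, against 1260 and 994 in WT and 683 in MCM22A. How reads that map to several places were counted is not stated, and no library known to lack Y gives a background. MCM22A, alone with reads in the single-copy genes (22), had the lowest rate here, so these reads need not follow the presence of Y. Absence of only the part before that position, which holds the single-copy genes, cannot be told apart from other causes either. Its 43 genes had 7 and 9 H3K9me3 reads in POLA1_hbm, at most 12.28% of the MCM22A rate (177 reads), but WT was as low with 13 and 11 reads (12.22 and 12.11%). So MCM22A was the exception, although RNA of WT replicate 2 had 10027 counts in these genes. The 8 single-copy genes examined had 0 reads in both POLA1_hbm and both WT libraries and 22 in MCM22A, where 7 X-linked relatives had 41 and 27, 21 and 12, and 75. Loss in some cells of MCM2_2A replicate 2 would lower Y genes by 1 factor. Log2 ratios to WT replicate 2 were -2.71 (Eif2s3y), -3.98 (Uty) and -4.77 (Ddx3y), a range of 2.06. WT is another genotype, so loss is not excluded. WT replicate 1 lay 0.373 (root mean square log2 difference) farther from the nearer POLA1_hbm library than from WT replicate 2. This argues against a mislabelled library of the POLA1_hbm batch. As batch and genotype cannot be told apart, it cannot exclude POLA1_hbm cells prepared together with the WT libraries. A mislabelled MCM2_2A library is excluded for WT replicate 1 by its Mcm2 level, 462 CPM against 273 and 312. A difference between clones was not tested.

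The major satellite GSAT_MM had more RNA (2.66 ± 0.37) and less H3K9me3 (-1.63 ± 0.10) in the MCM2-2A mutant. Its RNA call was lost without any one of the MCM2_2A or POLA1_hbm replicates. Lower enrichment of the single MCM22A library cannot be told apart from a loss of the mark there: the IAP subfamilies had a median H3K9me3 change of -0.42, lower too but by less, and no input library was used. A candidate explanation, that loss of H3K9me3 raises RNA, was tested over all repeats. Of the 34 repeats called lower in H3K9me3, 31 were also tested in RNA. Their median RNA log2 fold change was 0.36 against 0.21 in 822 others, a difference of 0.15 (permutation p = 0.00405). Of the 31, 3 were called higher in RNA against 16 of the 822. The 31 include GSAT_MM, which prompted the test, were called from a single mutant library on the TMM scale, and are not independent replicates. With total-count scaling fewer repeats were called lower and some higher. The Spearman correlation of RNA with H3K9me3 was weaker without RNA WT replicate 2 and at a mean log2 CPM of at least 2. The difference therefore does not decide whether loss of the mark raises RNA.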

How the results depend on the processing

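Fits without processed pseudogenes, fits to protein-coding genes and repeats, the H3K9me3 fits to the compared libraries total-count scaling of named H3K9me3 features and separate WT libraries for each mutant were chosen after seeing the data. No paired analysis was possible because the titles number only the second replicate of each genotype ("rep2") and nothing ties the libraries of different genotypes together. Main counts are 991, 5354 and 3343 genes and 19, 98 and 58 repeats (RNA: MCM2_2A against WT, POLA1_hbm against WT, POLA1_hbm against MCM2_2A), and 52, 137 and 31 features and 4, 34 and 13 repeats (H3K9me3: POLA1_hbm against WT, MCM22A against WT, POLA1_hbm against MCM22A). Counts of RNA genes stayed within 1.5 times of these with DESeq2, RLE scaling and the stricter filter. Where a count moved further, the cause was not tested, except that a minimum fold change leaves fewer features by construction.

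With a minimum log2 fold change of 1, RNA gene counts were 329, 1893 and 1172, RNA repeat counts 6, 21 and 22, H3K9me3 feature counts 19, 72 and 18, and H3K9me3 repeat counts 0, 5 and 2. Without a filter MCM2_2A against WT had 2470 genes, RNA repeats numbered 62, 165 and 102, H3K9me3 features 18, 62 and 18, and H3K9me3 repeats 1, 9 and 5. In fits to the compared libraries, MCM2_2A against WT had 113 genes and POLA1_hbm against MCM2_2A 5493, RNA repeats numbered 6, 49 and 91, H3K9me3 of POLA1_hbm against WT had 0 features and 0 repeats (edgeR; 812 and 190 unadjusted in the fit to all libraries), and MCM22A against WT 59 repeats. Adjustment over repeats alone gave 12, 48 and 37 RNA repeats.

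DESeq2 called 31 RNA repeats in MCM2_2A against WT. For H3K9me3 it called 0, 21 and 17 features and 0, 8 and 5 repeats. The stricter filter gave 134 features and 62 repeats in H3K9me3 of POLA1_hbm against WT, where RLE scaling gave 8 repeats and total counts 2. The file-name tag as a term gave 38 features and 20 repeats in MCM22A against WT.

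Leaving out 1 library gave 49 to 3612, 2030 to 6823 and 622 to 5581 RNA genes, 3 to 44, 46 to 131 and 21 to 96 RNA repeats, 16 to 103, 118 to 157 and 51 to 82 H3K9me3 features, and 2 to 31, 44 to 62 and 22 to 37 H3K9me3 repeats. The correlation of effects across genes was 0.471 at a mean log2 CPM of at least 2, 0.501 without processed pseudogenes and 0.443 to 0.595 without a WT replicate. Across repeats it was 0.394 at that minimum and 0.406 to 0.567 without a WT replicate. With MCM2_2A against WT replicate 1 and POLA1_hbm against WT replicate 2 it was 0.139 for genes and 0.067 for repeats, and the other way round 0.217 and 0.027. That division also leaves 1 control library for each mutant, so the parts played by shared controls, fewer controls and the difference between them were not separated. In the MCM2 mutant the Spearman correlation of RNA with H3K9me3 was -0.05 (permutation p = 0.35) at that minimum and -0.122 to -0.048 without 1 WT library. In POLA1_hbm it was 0.146 (permutation p = 0.00607) and 0.008 to 0.092. Mutant libraries were not left out for this correlation.

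Of the named calls, DESeq2 kept 57 of the 58 it tested in MCM2_2A against WT, 97 of 98 in POLA1_hbm against WT and 78 of 81 between the mutants in RNA. In H3K9me3 it kept 0 of 14, 5 of 5 and 5 of 5. The last 2 comparisons had 15 and 10 named calls, and DESeq2 gave the rest of them no adjusted p. In all refits run for named features that gave a value, 12 of 59, 71 of 98 and 31 of 81 RNA calls and 0 of 14, 6 of 15 and 5 of 10 H3K9me3 calls were kept. Of the named calls, only those of Y-linked genes in RNA POLA1_hbm against WT reversed, with counts near 0. Over all calls, 11 of the 52 H3K9me3 calls of POLA1_hbm against WT changed sign without POLA1_hbm replicate 2, as did 5 of 5452 RNA calls of that comparison without WT replicate 2. Ddx3y, RNA MCM2_2A against WT, was 13.03 without WT replicate 2, 0.10 without MCM2_2A replicate 2 and down to -3.78 without others. Without WT replicate 2, Ddx3y, RNA POLA1_hbm against WT, was 3.54 and Uty, RNA POLA1_hbm against WT, 2.19, and without others down to -13.84 and -12.83. Power was lowest in H3K9me3, where depth, number of libraries and spread act together: simulated 2-fold changes were recovered for 16, 20 and 16 of 100 features.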

Other observations

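The explanation of the Y-linked pattern was tested only after the result was seen, and the values here are given without further tests. Eif2s3y had 0.0901 and 86.6 CPM in the WT libraries, 65.1 and 13.2 in MCM2_2A and 0.0244 and 0 in POLA1_hbm, Uty 0 and 48.2, 35.3 and 3.05, and 0 and 0.0232, and Uba1y 0.03 and 6.44, 4.63 and 3.08, and 0 and 0. The imprinted H19 had 2.13 and 31.7 CPM in WT, 83.1 and 16.8 in MCM2_2A and 4.08 and 3.48 in POLA1_hbm, and Nnat 4.32 and 4.15, 23.3 and 1.38, and 0.269 and 0.0927, so both varied between replicates.

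Over all tested genes and repeats, WT replicate 2 lay closer to the MCM2_2A libraries (root mean square log2 differences of 0.469 and 0.485) than to WT replicate 1 (0.511). The first principal component of the RNA libraries held 56.9% and the second 21.6% of the variance. The chi-square per feature between replicates, which counting error alone would put near 1, was 20.43 (WT), 4.95 (MCM2_2A) and 14.51 (POLA1_hbm) in RNA and 8.20 (WT) and 6.46 (POLA1_hbm) in H3K9me3.

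Changes by autosome and on X were small: the median log2 fold change over the genes of 1 chromosome ran from -0.123 (X, MCM2_2A against WT) to 0.045 (16, POLA1_hbm against MCM2_2A) over the autosomes and X (20 chromosomes). The Y and mitochondrial genes were left out of that range. In POLA1_hbm against WT their medians were -9.992 (7 Y genes) and 0.373 (12 mitochondrial genes), and in POLA1_hbm against MCM2_2A -9.473 and 0.156. The Spearman correlation of fold changes with GC content or gene length did not exceed 0.126 in size (-0.126 for length in POLA1_hbm against WT).

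In H3K9me3, reads counted in annotated Y genes were 1309 and 1038 per 1e+06 in WT, 1309 and 1484 in POLA1_hbm and 760 in MCM22A, in which IAPEy-int and MURVY-int, repeats with copies on Y, were lower as well. Mitochondrial reads took 0.863 and 0.909% in WT, 1.04 and 0.371% in POLA1_hbm and 0.544% in MCM22A.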
